A study of Danio rerio with 15 samples.

How the data were processed

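Neutrophils sorted from zebrafish embryos were sequenced in 15 libraries, 3 for each of 5 groups, and the groups were taken from the titles in the labels. RNA was isolated with a column kit for small samples and libraries were made with a TruSeq RNA v2 kit, per the labels' protocols. That kit does not mark strand, so reads of overlapping and antisense genes cannot be told apart. TopHat, Cufflinks and DESeq2 were used, per the submitters' processing notes, which give no versions. The genome build, the annotation and the counting program are not given in the sources used here.

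The deposited table gives a signal per gene and library, which are read counts that the authors divided by a size factor for each library. This reading comes from the values: in each library they are whole multiples of the value of 1 read. All 100% of values came out whole after division by that step, with a largest deviation of 9.3e-05 reads and a tolerance of 0.01. Recovered totals ran from 5.64 to 31.06 M reads. A floor of 3 reads per library was used for genes at 0, and it covers counting error only. The table has 15937 genes, of which 15194 identifiers are in the gene name table used here. 15 symbols had been turned into dates by spreadsheet software, and 14 were restored by identifier. All per-sample columns matched a sample.

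The main test was limma 3.58.1 (R 4.3.3) on log2(value + 1) with a mean-variance trend and robust moderation, fitted to all 15 libraries with 5 group means. Genes needed a value of at least 10 in at least 3 libraries, which kept 15933 and removed 4. Tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. A count test was not the main one because the file holds normalised values; edgeR 4.0.16 and DESeq2 1.42.0 were run on the recovered reads as alternatives. 24 gene lists were fixed, with 517 of 576 entries tested. 23 lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists within a comparison, and the list of lens, yolk and liver markers had 4 tested members and was not tested. No list in any of the 8 comparisons passed camera with an estimated correlation.

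Groups, tests, lists, the rule for named genes and the alternatives were fixed before the data were examined, except those said to have been chosen later, among them the comparisons of double mutants with each single mutant. Named genes are tet2, tet3, tet1, socs3b, mpx and lyz always. To these come the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 50 in the higher group, no overlap between the groups' libraries and a symbol that is not a clone name. From each list up to 4 members with the smallest p were taken. For the interaction the overlap was judged between double mutants and wildtype.

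Replicate pairs differed by 4.01 to 90.56 times sampling noise, so no library is a copy of another of its group. Pairs from different groups were not tested in this way. The steps were tested on simulated data for the comparison of double mutants with wildtype over 15933 genes. limma recovered 17 of 100 genes changed 2-fold and 77 of 100 changed 4-fold with 0 false calls, edgeR 18 and 78 with 0, and DESeq2 31 and 87 with 31. The simulation drew genes independently and gave each gene the same spread in all groups. It therefore does not test false calls under the unequal spread of the real groups. Genes near tet2 were found with a RefSeq gene table of another or unknown build, used only for which genes neighbour each other, and it placed 90.5% of tested genes. Alternatives covered the pseudocount, the filter, the scaling, the test, the libraries in the fit, library weights, a replicate block, each library left out, and, chosen after the data were seen, reads thinned to 1 depth, the shallow tet3 libraries left out together and hsp70l as a covariate.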

Results

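The study profiled polyadenylated RNA of neutrophils from zebrafish embryos in 15 libraries. Neutrophils were sorted on green fluorescent protein driven by the promoter of mpx, the myeloperoxidase gene. The libraries form 5 groups of 3. At 2 days post fertilization (dpf) the groups are wildtype, tet2 mutant, tet3 mutant and tet2/tet3 double mutant embryos. A further wildtype group was taken at 1.5 dpf, given in the labels as 35 hours. Tet2 and Tet3 are dioxygenases that oxidise 5-methylcytosine. Read totals recovered from the deposited values, in M (mega) reads, were 12.18, 14.84 and 13.89 M in wildtype at 2 dpf and 12.19, 13.01 and 15.05 M in wildtype at 1.5 dpf. They were 13.29, 13.8 and 13.5 M in tet2 mutants, 5.64, 5.96 and 13.65 M in tet3 mutants, and 31.06, 27.39 and 27.19 M in double mutants. Values below are normalised read counts, given as mean ± SD over n = 3 libraries per group. Fold changes come from limma on log2(value + 1), which understates the change of low genes. Adjusted p-values are limma's with Benjamini-Hochberg adjustment over 15933 genes. The labels do not say whether the libraries of a group came from separate clutches or sorts, so these p-values measure the spread between these libraries, which may be technical. That spread was pooled over the 5 groups, so the p-values of a comparison also reflect groups it does not compare. The groups differed in spread: replicates correlated at 0.956 to 0.967 in wildtype at 2 dpf, 0.941 to 0.942 in tet3 mutants, 0.885 to 0.94 in tet2 mutants and 0.881 to 0.944 in double mutants.

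The targeted genes were measured first. tet2 mRNA was 1713 ± 176 in wildtype at 2 dpf, 1643 ± 304 in tet2 mutants, 1152 ± 187 in tet3 mutants and 1503 ± 973 in double mutants. tet3 mRNA was 1374 ± 230 in wildtype, 1663 ± 379 in tet2 mutants, 1993 ± 399 in tet3 mutants and 2324 ± 665 in double mutants. Neither gene passed the test in any mutant against wildtype. The limma adjusted p of tet2 was 0.99 in tet2 mutants and 0.56 in double mutants, and that of tet3 was 0.26 in tet3 mutants and 0.1 in double mutants. A count over the whole transcript does not show whether a mutant allele is present, so these values neither support nor contradict the genotype labels. tet1, the remaining member of the family, was 421 ± 118 in wildtype and 458 ± 263 in double mutants (adjusted p = 1 by limma).

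**Figure D1:**
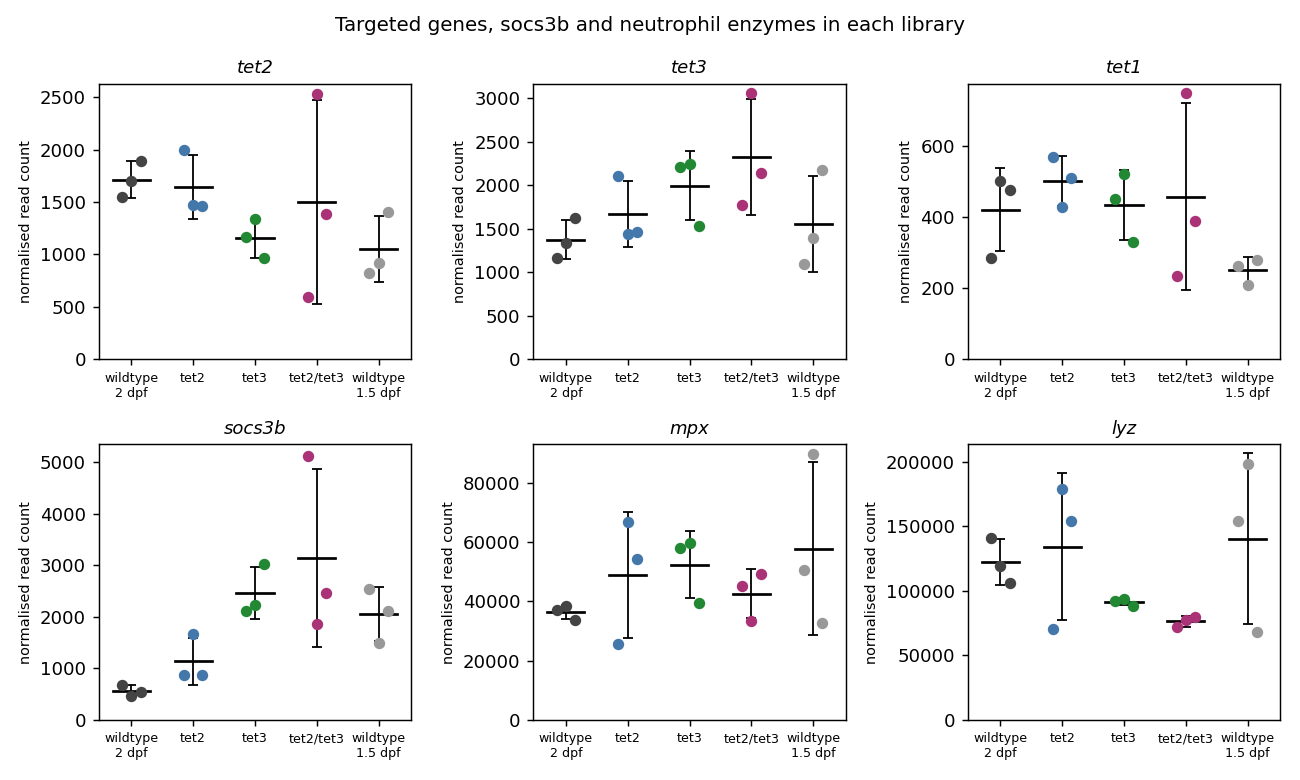
Normalised read counts (vertical axes, linear from 0) of tet2, tet3, tet1, socs3b, mpx and lyz in the 5 groups; points are the 3 libraries of a group, the wide bar is the mean and the whiskers are 1 SD. The socs3b means were 561 in wildtype at 2 dpf, 1134 in tet2 mutants, 2456 in tet3 mutants, 3142 in double mutants and 2051 in wildtype at 1.5 dpf.

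The libraries also differed in heat shock transcripts, which were singled out after their values were seen. hsp70l and hsp70.3, near-identical heat-inducible chaperone genes whose reads may be split between copies, together took 3.523, 4.138 and 3.959% of all normalised counts in wildtype at 2 dpf. Their share was 3.459, 2.182 and 4.884% in tet2 mutants and 0.299, 0.3 and 0.279% in tet3 mutants. It was 0.079, 1.887 and 0.603% in double mutants and 0.089, 0.106 and 0.057% in wildtype at 1.5 dpf. The labels give no batch, sorting day or library preparation date, so no value within batches can be given.

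**Figure D2:**
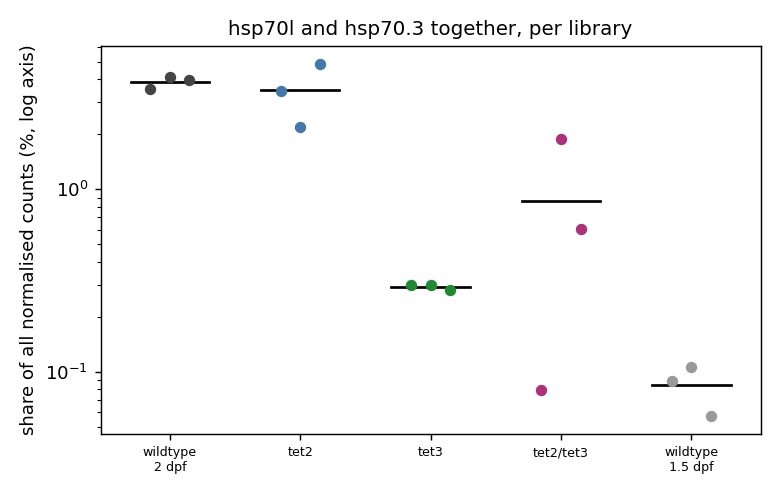
Share of all normalised counts (vertical axis, percent, log scale) taken by hsp70l and hsp70.3 together in each library; points are libraries and bars are group means. The 3 wildtype libraries at 2 dpf lie between 3.523 and 4.138%, and the 3 double mutant libraries spread from 0.079 to 1.887%.

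The main comparison asked how loss of both tet2 and tet3 changes the neutrophil transcriptome at 2 dpf. socs3b, a suppressor of cytokine signalling, rose from 561 ± 109 in wildtype to 3142 ± 1730 in double mutants (log2 change 2.36, SE 0.34, adjusted p = 0.00045 by limma). Several genes of endothelial cells were lower in double mutants, among them stab1 and stab2, which encode scavenger receptors of lymphatic, venous and macrophage lineages. Several genes of pigment cells were higher, including the transcription factor gene sox10. The main neutrophil enzyme genes did not pass the test: mpx was 36480 ± 2400 in wildtype and 42550 ± 8270 in double mutants, and lyz, which encodes lysozyme, was 122000 ± 17900 and 76300 ± 4140. Across the transcriptome 1383 genes changed, 544 higher and 839 lower. Heat shock transcripts moved with these groups, with a smaller share in double mutants than in wildtype.

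Among endothelial markers none of 22 tested members rose, 9 fell and 13 did not pass, and 17 fell when adjusted over the list alone. stab1 fell from 2059 to 187 (log2 change -3.47, adjusted p = 2.5e-05 by limma), stab2 from 1729 to 276, etv2, a transcription factor gene of vascular progenitors, from 235 to 63.1, and fli1a from 2101 to 955. The list was lower by camera (median log2 change -1.14, adjusted p = 9.8e-10), with an adjusted p = 0.38 with an estimated correlation. Pigment cell markers had 6 risers among 13 members, no faller, and 10 risers adjusted over the list alone. sox10 rose from 298 to 3010 (log2 change 3.28, adjusted p = 5.9e-06 by limma), slc45a2, a melanosome transporter gene, from 34.8 to 679, gpr143 from 42.2 to 399, and paics, a purine synthesis gene, from 748 to 2531. The camera adjusted p of this list was 3.1e-09 (median 2.48), and adjusted p = 0.38 with an estimated correlation.

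Of 22 macrophage markers 2 rose and 6 fell, the same counts as adjusted over the list alone. lgals3bpb fell from 4422 to 162 (log2 change -5.01, adjusted p = 9e-06 by limma), and the complement genes c1qa and c1qb fell from 144 to 10.2 and from 253 to 31.9. The list was lower by camera (adjusted p = 0.0025, and adjusted p = 0.91 with an estimated correlation). Of 16 myeloid transcription factors 2 rose and 3 fell, against 2 and 7 adjusted over the list alone. irf8, a regulator of the macrophage fate, fell from 2027 to 806 and gfi1b from 90.5 to 24, while cebpg rose from 673 to 1275. camera gave this list an adjusted p of 0.022, and adjusted p = 0.91 with an estimated correlation, and without double mutant replicate 2 the list did not pass (adjusted p = 0.095). Of 24 muscle markers 4 fell and none rose, with 5 falling adjusted over the list alone. tnnt2a fell from 107 to 12.4 and ttn.2 from 1619 to 321 (camera adjusted p = 0.00012, and adjusted p = 0.91 with an estimated correlation). On the statistics of edgeR and DESeq2 the muscle list did not pass (camera adjusted p = 0.25 and 0.31). Of 23 neural markers 2 rose, also when adjusted over the list alone. neurod1 rose from 54.5 to 349 and sox19a from 280.3 to 1020 (camera adjusted p = 0.00071, and adjusted p = 0.91 with an estimated correlation). neurod1 did not pass without wildtype replicates 1 or 3 or double mutant replicates 1 or 3. sox19a did not pass when any 1 wildtype replicate was left out, nor without double mutant replicates 2 or 3. Neither gene passed with hsp70l as a covariate.

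Of 28 immediate early and heat shock genes 10 fell, 1 rose and 17 did not pass, against 13 falling and 3 rising adjusted over the list alone. The AP-1 genes jun and fosab fell from 29590 to 11760 and from 24020 to 8377, and dusp1, a phosphatase gene, from 11720 to 4642. ier5l rose from 1130 to 4761. The list had a camera adjusted p of 0.0013, and adjusted p = 0.38 with an estimated correlation. Single genes of signalling lists moved both ways. jak3, a kinase of cytokine receptors, fell from 988 to 115 (log2 change -3.08, adjusted p = 7.2e-06 by limma), and mcl1a, an anti-apoptotic gene, fell from 58350 to 9187. il1b, an inflammatory cytokine gene, fell from 8020 to 1457, and the interferon-responsive genes isg15 and mxc fell from 585 to 37.5 and from 80 to 4.91. tnfaip2b rose from 59.2 to 345.

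The JAK-STAT list had 3 risers and 3 fallers among 28 members, against 4 and 4 adjusted over the list alone, and a camera adjusted p of 0.83. Its median was -0.06 and its mean 0.03. The inflammatory list had 2 risers and 4 fallers of 23 (4 and 6 adjusted over the list alone), the interferon list 2 fallers of 13 (also 2), and the unfolded protein response list 1 riser and 2 fallers of 21 (also 1 and 2). Granule products had 0 of 12 members past the limma threshold, methylation enzymes 0 of 22, cell cycle genes 0 of 28, ribosomal proteins 0 of 35 and oxidative phosphorylation genes 0 of 25. Neutrophil receptors had 1 faller of 21, wasb, which fell from 2743 to 621. The secretory list had 1 riser and 2 fallers of 33, the p53 target list 1 riser of 17 and the progenitor list 2 risers and 2 fallers of 17, the same as adjusted over each list alone. Epidermis markers had 2 risers and 1 faller of 21 (2 and 2 adjusted over the list alone), erythroid markers 1 riser and 1 faller of 23 (1 and 3), and glycolysis genes 1 faller of 25 (0). None of these 16 lists passed the camera threshold with all libraries. Ribosomal proteins passed as higher without wildtype replicate 1 (camera adjusted p = 0.00043) and without double mutant replicates 2 (0.023) and 3 (0.0014). Oxidative phosphorylation genes passed as higher without wildtype replicate 1 (0.0074) and double mutant replicate 2 (0.0035), and erythroid markers without double mutant replicate 2 (0.023).

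By size of change, the falls in double mutants were led by cmn (1269 ± 517 to 4.78 ± 6.94), ngs, nid2b, ankrd1b, fut9b and eef1a1b, followed by tnnc1b, col9a1b, abraa and myl4. Of these, cmn, tnnc1b and abraa did not pass when any 1 wildtype replicate was left out. cmn and abraa also did not pass without double mutant replicates 2 or 3. nid2b encodes a basement membrane protein, col9a1b a cartilage collagen, and tnnc1b and myl4 muscle proteins. nid2b fell from 151 ± 5.31 to 1.41 ± 2.45 (log2 change -6.45, SE 0.98, adjusted p = 0.00064 by limma), and fut9b from 224 ± 29.5 to 3.07 ± 3.19. The rises were led by POU2AF1 and dbh, which were at 0 in all wildtype libraries at 2 dpf. Against a floor of 3 reads per library POU2AF1 was at least 22.7-fold higher (mean 84.5 ± 30.1) and dbh, the noradrenaline synthesis enzyme gene, at least 30.7-fold higher (mean 114 ± 94.4). dbh did not pass when any 1 wildtype replicate was left out, nor without double mutant replicates 1 or 3. It also did not pass with a pseudocount of 0.5 or a filter at a value of 50. ednrba, an endothelin receptor gene, rose from 7.52 ± 7.07 to 269 ± 151, and prdm8 from 1.81 ± 2.19 to 82.7 ± 28.4. PRTFDC1, cldne, cyp4t8, ocstamp, MREG and SYNPR completed the 10 largest rises, with log2 changes between 4.4 and 5.4. eef1a1b and ednrba are among the 100 tested genes nearest to tet2, and isg15 among those nearest to tet3. Of these neighbours 7 and 10% had an unadjusted p under 0.01 in double mutants, against 11.8% of other genes (Fisher exact p = 0.16 and 0.75).

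The count of 1383 fell to 793, 713 and 688 without wildtype replicates 1, 2 and 3 and to 772 without double mutant replicate 3. DESeq2 called 2093 genes on the recovered reads, and limma with each library's hsp70l level as a covariate, a setting chosen after the data were seen, called 159. In that fit socs3b no longer passed in double mutants (log2 change 1.15), while stab1 (-3.56), sox10 (2.42), lgals3bpb (-5.95) and jak3 (-2.83) still did. Of 50 genes named in this comparison that had passed, 14 still passed and 36 did not, and with single libraries left out 41 to 47 passed. Those that did not include all 10 of the largest rises, the endothelial genes stab2 (-1.74), etv2 (-1.88) and fli1a (-0.84), the pigment genes slc45a2 (3.39), gpr143 (2.42) and paics (1.41), and irf8 (-1.99), il1b (-2.66) and isg15 (-2.72).

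**Figure D3:**
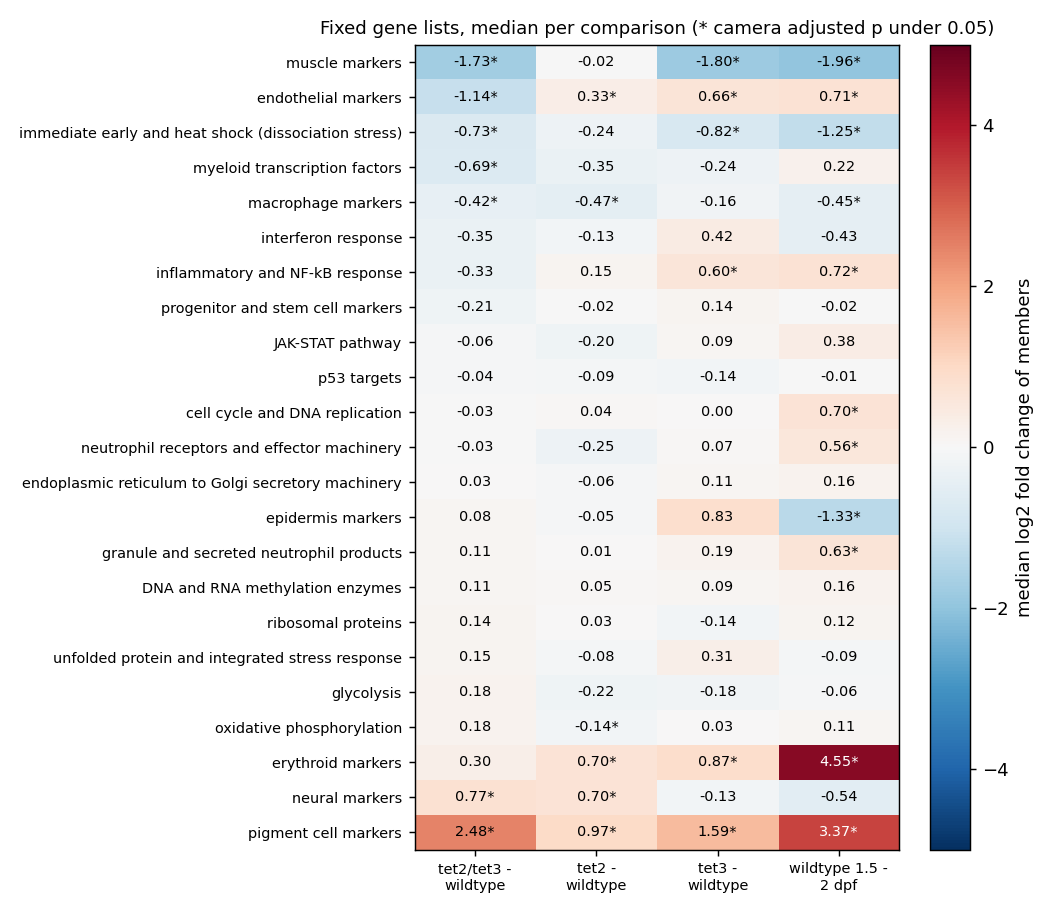
Median log2 fold change of the members of 23 gene lists (rows, ordered by the double mutant value) in 4 comparisons (columns); colour and printed number give the median, and an asterisk marks a camera adjusted p under 0.05 with the preset correlation. Pigment cell markers were higher in all 4 columns, and endothelial markers were lower only in the double mutant column (median -1.14 against 0.33, 0.66 and 0.71).

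Few genes were called in tet2 mutants, whose libraries differed among themselves. 16 genes changed, 5 higher and 11 lower, and 1002 had an unadjusted p under 0.05. tgm2l, a transglutaminase gene, fell from 590.1 ± 116 to 72 ± 44.2 (log2 change -3.18, adjusted p = 0.03 by limma), eef2a.2 from 115 ± 17.5 to 19.1 ± 6.52, ugt5b2, a glucuronosyltransferase gene, from 134 ± 10.3 to 27 ± 8.92, and gpx4a, a glutathione peroxidase gene, from 326 ± 45.6 to 98.7 ± 25.6. The zinc finger genes znf1179 and znf1028 rose from 23.1 ± 8.78 to 210 ± 96.6 and from 5.86 ± 2.15 to 57.5 ± 23.9. In double mutants tgm2l averaged 360.2, eef2a.2 95.98, ugt5b2 57.1 and gpx4a 218.2, all above tet2 mutants. The zinc finger genes averaged 231.7 and 68.58 there, 389 and 37.93 in tet3 mutants, and 62.65 and 43.72 in wildtype at 1.5 dpf. The falling genes were picked for their low values in tet2 mutants, so higher means elsewhere do not show an effect of also losing tet3. The rises were not particular to tet2 mutants. socs3b did not pass (561 ± 109 and 1134 ± 453, log2 change 0.96, adjusted p = 0.6 by limma). Over all genes tet2 replicate 1 correlated with the wildtype libraries at 0.87 to 0.892, about as tet3 libraries did (0.877 to 0.905), and replicate 3 at 0.95 to 0.96, so the count does not measure closeness to wildtype. With only these 2 groups in the fit none of the 6 named genes passed, and without wildtype replicates 1, 2 or 3 only znf1179 did. Without tet2 replicates 1 or 2 in turn 2 of them passed, ugt5b2 and znf1179.

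No member of any of the 23 lists passed over all genes tested in tet2 mutants. camera with its preset correlation called neural (median 0.7), pigment (0.97), erythroid (0.7) and endothelial markers (0.33) higher and macrophage markers (-0.47) and oxidative phosphorylation genes (-0.14) lower. Each of these 6 had an adjusted p = 0.96 with an estimated correlation. On reads thinned to 1 depth the endothelial (0.06) and oxidative phosphorylation (0.069) lists did not pass. Leaving out tet2 replicate 3 raised the count to 85, with 1936 at an unadjusted p under 0.05, and it was 7, 8 and 7 without wildtype replicates 1, 2 and 3 and 10 without tet2 replicate 2. With only these 2 groups in the fit limma called 0 genes, with 931 at an unadjusted p under 0.05, while edgeR and DESeq2 on all libraries called 12 and 111. Quantile normalization gave 32.

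The tet3 mutants changed more broadly, with 588 genes higher and 571 lower than wildtype, 1159 in all. socs3b rose to 2456 ± 502 (log2 change 2.13, SE 0.34, adjusted p = 0.0019 by limma). Genes of slow muscle were among the largest falls: smyhc1, a slow myosin heavy chain gene, from 3839 ± 340 to 47.5 ± 75.9 (log2 change -8.51, adjusted p = 0.0078 by limma), myl10 from 2329 ± 311 to 47.9 ± 76.6, and tnni1c from 418 ± 86.6 to 7.51 ± 13. isg15 fell from 585 ± 57.2 to 3.38 ± 5.85. It is among the 100 tested genes nearest to tet3, so a variant linked to the mutated locus stays open for it, but it was also low in wildtype at 1.5 dpf (11.65 ± 2.54). Of these neighbours 10 had an unadjusted p under 0.01, against 1596 of 14326 other genes (Fisher exact p = 0.87). The chaperone genes hspb1 and hsph1 fell from 41090 ± 258 to 309 ± 35.6 and from 54530 ± 5880 to 475 ± 49.4. pglyrp6, MYH6, myl13 and mybpc1 were the others among the 10 largest falls.

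Of 22 endothelial markers 6 rose in tet3 mutants and none fell, with 9 rising adjusted over the list alone. cdh5, which encodes vascular endothelial cadherin, rose from 216 to 1069 (log2 change 2.3, adjusted p = 0.015 by limma), clec14a from 78.7 to 320 and cldn5b from 61.7 to 207. lyve1a, a hyaluronan receptor gene of lymphatic endothelium, rose from 74.2 ± 26 to 1212 ± 476. The camera adjusted p was 0.00085, and adjusted p = 0.97 with an estimated correlation. Among the other largest rises were gata4, a cardiac and endodermal transcription factor gene (0.791 ± 1.37 to 102 ± 14.8), lpar5b (18.6 ± 14 to 400 ± 92.5), sox8a (18.3 ± 4.17 to 331 ± 52.3) and znf1179 (23.1 ± 8.78 to 389 ± 67.7), with PRTFDC1, ednrba, cyp4t8 and ocstamp and a gene of the MFAP4 family. MFAP4 genes are near-identical copies, and their values are uncertain.

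Of 23 inflammatory genes 7 rose and 2 fell in tet3 mutants (7 and 3 adjusted over the list alone). Those that rose include the chemokine gene cxcl18b (359 to 1670, log2 change 2.27, adjusted p = 0.00016 by limma), irg1, an enzyme gene of activated myeloid cells (3108 to 29650), and tnfaip2b (59.2 to 236). camera gave an adjusted p of 0.0045, and adjusted p = 0.97 with an estimated correlation. Among JAK-STAT members 5 of 28 rose and 1 fell (10 and 3 adjusted over the list alone). This list did not pass by camera (adjusted p = 0.14, and adjusted p = 0.97 with an estimated correlation). il6, a cytokine gene, rose from 237 to 2655 (log2 change 3.5, adjusted p = 0.016 by limma) and its receptor subunit gene il6st from 998 to 2313. Pigment markers had 4 risers of 13, with 5 adjusted over the list alone, and sox10 rose from 298 to 2140 (camera adjusted p = 4.4e-05, and adjusted p = 0.97 with an estimated correlation). Muscle markers had 5 fallers of 24, with 6 adjusted over the list alone (camera adjusted p = 3e-04, and adjusted p = 0.97 with an estimated correlation). Heat shock and immediate early genes had 11 fallers and 1 riser of 28, with 14 and 2 adjusted over the list alone (camera adjusted p = 1.3e-05, and adjusted p = 0.27 with an estimated correlation). Erythroid markers had 1 riser of 23, slc25a37, and the same count adjusted over the list alone (camera adjusted p = 0.00077, and adjusted p = 0.97 with an estimated correlation).

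The tet3 count was 473, 424 and 382 without wildtype replicates 1, 2 and 3, and 426, 442 and 749 without tet3 replicates 1, 2 and 3. With hsp70l as a covariate it was 21. A fit without the 2 shallower tet3 libraries together left 1 tet3 library, so only its effect sizes are given. Both settings were chosen after the data were seen. With only tet3 mutants and wildtype in the fit the count was 3912. Of 31 genes named in this comparison that had passed, 2 still passed with the covariate and 22 to 29 with single libraries left out. Without tet3 replicates 1 or 2 in turn, cdh5, clec14a, cldn5b and lyve1a were among those lost, and il6 was lost without wildtype replicates 1 or 3. With the covariate cdh5 (3.95) and smyhc1 (-11.45) lost their calls although their log2 changes were larger than without it, while those of il6 (2.49) and hspb1 (-2.03) were smaller. The covariate is confounded with group, so a lost call does not show that hsp70l accounts for a change. socs3b did not pass with the covariate (log2 change 0.6), and its log2 change was 2.45 without the shallower libraries.

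**Figure D4:**
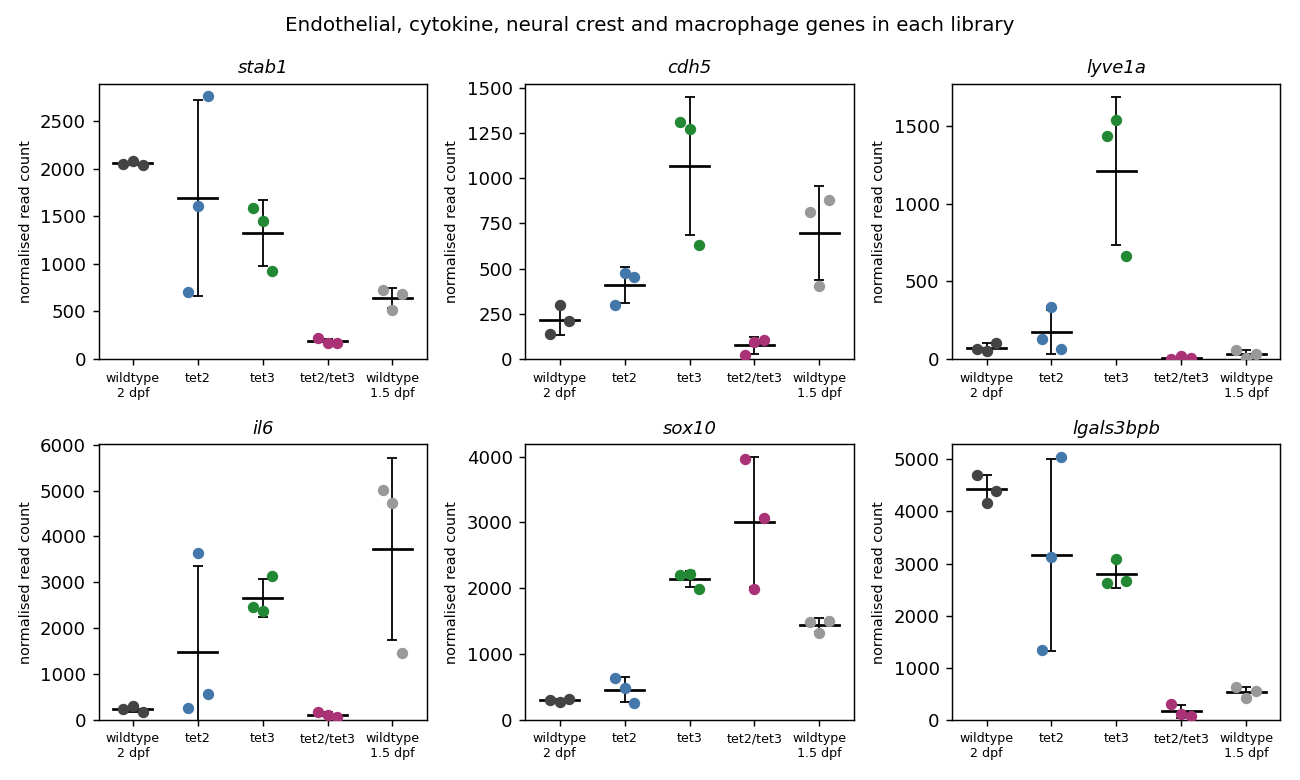
Normalised read counts (vertical axes, linear from 0) of stab1, cdh5, lyve1a, il6, sox10 and lgals3bpb in the 5 groups; points are libraries, the wide bar is the mean and the whiskers are 1 SD, not drawn below 0. cdh5 averaged 1069 in tet3 mutants and 75.5 in double mutants, and il6 averaged 2655 and 114.

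The wildtype stages were compared to show how neutrophil preparations differ between 1.5 and 2 dpf. Red cell genes were higher at 1.5 dpf: all 23 erythroid markers rose, also when adjusted over the list alone (median log2 change 4.55). slc4a1a, the band 3 anion exchanger gene, was 13340 at 1.5 dpf and 509 at 2 dpf (log2 change 4.79, adjusted p = 2.8e-05 by limma), tfr1a, a transferrin receptor gene, 2937 and 171, klf1 378 and 25.8, and sptb 4319 and 459. hbbe3, a globin gene, was 40550 ± 6200 and 613 ± 220. Globin genes are near-identical copies, so values of single copies are uncertain. The camera adjusted p was 1.5e-24, and adjusted p = 0.086 with an estimated correlation. Altogether 3317 genes changed, 1462 higher and 1855 lower at the younger stage.

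Proliferation genes were also higher in the younger preparations, with 22 of 28 cell cycle genes rising and 26 adjusted over the list alone. The values do not tell whether neutrophils or erythroid cells in these libraries carried them. rrm2, a ribonucleotide reductase gene, was 1799 against 569.7, plk1 3250 against 1779 and bub1 1527 against 822 (camera adjusted p = 4.2e-12, and adjusted p = 0.27 with an estimated correlation). Pigment markers had 11 risers of 13 and 13 adjusted over the list alone, including dct, the dopachrome tautomerase gene (617 against 24), and sox10 (1439 against 298), with a camera adjusted p of 4.9e-09 and an adjusted p = 0.27 with an estimated correlation. Endothelial markers had 8 risers and 1 faller of 22, the same adjusted over the list alone, with sox18 at 616 against 123 and stab1 at 643 against 2059 (camera adjusted p = 0.0049, and adjusted p = 0.83 with an estimated correlation). Inflammatory genes had 8 risers and 3 fallers of 23 (9 and 3 adjusted over the list alone), with il6 at 3725 against 237 and tlr5b at 1104 against 239 (camera adjusted p = 0.033, and adjusted p = 0.83 with an estimated correlation). csf3a, a colony-stimulating factor gene, was 2826 against 142. socs3b was 2051 ± 530 against 561 ± 109 (log2 change 1.85, adjusted p = 0.0016 by limma).

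Heat shock and immediate early genes were lower at 1.5 dpf, with 17 fallers and 2 risers of 28 (18 and 2 adjusted over the list alone; camera adjusted p = 6.8e-07, and adjusted p = 0.1 with an estimated correlation). The chaperone genes hsph1 (100.4 ± 26.9 against 54530 ± 5880), bag3, DNAJA4 and hspb1 were among the 10 largest falls. chs1, a chitin synthase gene, was at 0 in all 3 libraries at 1.5 dpf, at least 39-fold lower than the mean of 138 ± 46.4 at 2 dpf. Macrophage markers had 7 fallers and 1 riser of 22, the same adjusted over the list alone, with lgals3bpb at 527 against 4422 (camera adjusted p = 0.0084, and adjusted p = 0.83 with an estimated correlation). Epidermis markers had 7 fallers and 1 riser of 21, the same adjusted over the list alone, with krt5 at 621 against 4686 (camera adjusted p = 0.0018, and adjusted p = 0.83 with an estimated correlation). Muscle markers had 2 fallers of 24, also 2 adjusted over the list alone (camera adjusted p = 0.014, and adjusted p = 0.83 with an estimated correlation). Of the neutrophil lists, receptors had 2 risers of 21 (1 adjusted over the list alone), among them csf3r (3668 against 2410), and granule products had 1 riser of 12 (1 adjusted over the list alone), mmp13a (14440 against 5063). Their camera adjusted p-values were 0.0084 and 0.033, each with an adjusted p = 0.83 with an estimated correlation. The call of csf3r was lost when any 1 wildtype library of either stage was left out. It was also lost with quantile normalization, thinned reads, edgeR and the replicate block. Without wildtype 2 dpf replicates 2 and 3 in turn the count was 1930 and 1845, and without 1.5 dpf replicate 1 it was 1949. With hsp70l as a covariate it was 41, with 2 of 25 genes named in this comparison still past the threshold, and socs3b did not pass and had the opposite sign (log2 change -0.11).

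The departures of double mutants and of younger wildtype cells from wildtype at 2 dpf were compared to see whether the double mutant resembles an earlier stage. Across genes the log2 changes had a Pearson correlation of 0.5, and genes are not independent replicates. Both use the same 3 wildtype libraries, and simulated unchanged groups sharing them gave 0.5 over 100 simulations. That value follows from the shared control and the equal spread given to every simulated group, on which the simulated covariance also rests. The covariance was 0.48 against a simulated 0.1, a difference of 0.38. 262 genes were higher in both and 424 lower in both, against 49.9 and 97.7 for independent lists, and 29 changed in opposite directions. The 3 control libraries cannot be split with at least 2 on each side, so part of the excess may come from the shared controls. With tet2 mutants in place of wildtype as the reference for double mutants, a setting without shared libraries chosen after the data were seen, the correlation was 0.37. The hsp70l and hsp70.3 share was lower in double mutants and younger cells than in wildtype at 2 dpf and tet2 mutants. Neither reference therefore separates the similarity from heat shock state.

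Double mutants and younger wildtype cells were also compared directly, and 2258 genes differed, 1240 higher and 1018 lower in double mutants. Erythroid markers were lower in 21 of 23 and cell cycle genes in 17 of 28 (22 and 25 adjusted over the list alone), with slc4a1a at 669 ± 416 against 13340 ± 675 and cdk1 at 1240 ± 322 against 2419 ± 225. Endothelial markers were lower in 19 of 22, also 19 adjusted over the list alone, including sox18 (55.5 ± 2.44 against 616 ± 208, log2 change -3.39, adjusted p = 6.7e-06 by limma). Neural markers were higher in 11 of 23 (13 adjusted over the list alone), including elavl4 (1328 ± 950 against 160 ± 87.2). The camera adjusted p-values of these 4 lists were 3.3e-25, 1.3e-14, 2.6e-17 and 0.00013. In the same order the values were adjusted p = 0.079, 0.19, 0.16 and 0.75 with an estimated correlation. Epidermis markers had 7 risers of 21 (also 7 adjusted over the list alone), and heat shock and immediate early genes 5 risers and 1 faller of 28 (6 and 1). Inflammatory genes had 1 riser and 6 fallers of 23 (2 and 8), and myeloid transcription factors 1 riser and 5 fallers of 16 (1 and 7). Neutrophil receptors had 5 fallers of 21 (7), and granule products 2 of 12 (2). The camera adjusted p-values of these 6 lists were 0.00013, 0.001, 0.0013, 0.00021, 0.00021 and 0.023, with adjusted p = 0.75, 0.27, 0.75, 0.27, 0.75 and 0.81 with an estimated correlation. il1b and il6 were lower in double mutants (1457 ± 438 against 17820 ± 7900, and 114 ± 57.3 against 3725 ± 1980). socs3b did not pass (adjusted p = 0.34 by limma). The count was 1144 and 1460 without 1.5 dpf replicates 1 and 2 and 1282 without double mutant replicate 2. It was 1150 with only these groups in the fit and 1057 with hsp70l as a covariate.

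An interaction term asked whether the double mutant departs from the sum of the single mutants on the log2 scale. 53 genes passed, 7 above and 46 below the sum, and 1295 had an unadjusted p under 0.05. Endothelial markers lay below the sum in 7 of 22 members and above it in none, with 19 below adjusted over the list alone (camera adjusted p = 1.7e-31, and adjusted p = 0.05 with an estimated correlation, which did not pass). cdh5 was 216 ± 82.7 in wildtype, 410 in tet2 mutants, 1069 in tet3 mutants and 75.5 ± 46.1 in double mutants (interaction -4.98, SE 0.73, adjusted p = 0.0071 by limma), and kdr, a vascular growth factor receptor gene, was 81.5, 141, 283 and 31.8. Inflammatory genes lay below the sum in 2 of 23 members (5 adjusted over the list alone; camera adjusted p = 6.1e-06, and adjusted p = 0.67 with an estimated correlation). il6 was 237, 1489, 2655 and 114 in the same order (interaction -6.46, adjusted p = 0.02 by limma), and cxcl18b was 359, 677, 1670 and 906. socs3b did not pass (interaction -0.72, SE 0.48, adjusted p = 0.79 by limma). The count was 20 and 27 without wildtype replicates 2 and 3, 141 without tet2 replicate 1, and 24 and 14 without tet3 replicates 1 and 2. It was 236 with DESeq2 and 81 with hsp70l as a covariate. Without wildtype replicates 2 or 3, tet3 replicates 1 or 2, or double mutant replicates 2 or 3, il6 did not pass. cxcl18b also did not pass in these 6 settings, nor without tet2 replicates 2 or 3, tet3 replicate 3 or double mutant replicate 1, and kdr did not pass without wildtype replicate 2 or tet3 replicates 1 or 2.

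Double mutants were compared with each single mutant after the data had been examined. Against tet3 mutants 372 genes differed, 97 higher and 275 lower. Endothelial markers were lower in 15 of 22 and higher in none (21 adjusted over the list alone; camera adjusted p = 2.3e-28, and adjusted p = 0.07 with an estimated correlation), and macrophage markers lower in 7 of 22 (8 adjusted over the list alone; camera adjusted p = 1.6e-05, and adjusted p = 0.58 with an estimated correlation). lyve1a was 8.94 ± 11.5 in double mutants and 1212 ± 476 in tet3 mutants (log2 change -7.65, adjusted p = 0.00042 by limma), il6 114 ± 57.3 and 2655 ± 418, and jak3 115 and 537. Among the 10 largest rises in double mutants were otpb (767 ± 256 against 45.4 ± 31.1), gsx1, lbx1b and meox2b. Neural markers had 1 riser of 23 and no faller (also 1 adjusted over the list alone), and pigment markers no riser of 13 (2). Ribosomal proteins had 0 of 35 members past the limma threshold (0), with a median log2 change of 0.28. Inflammatory genes had 3 fallers of 23 (5), JAK-STAT members 2 of 28 (3) and myeloid transcription factors 0 of 16 (2). Erythroid markers had 2 fallers of 23 (1 riser and 4 fallers adjusted over the list alone), and interferon genes 1 riser and 1 faller of 13 (also 1 and 1). The camera adjusted p-values of these 8 lists were 6.5e-07, 0.005, 3.5e-05, 7.5e-07, 0.013, 0.00042, 0.021 and 0.01, with adjusted p = 0.58, 0.7, 0.72, 0.55, 0.72, 0.54, 0.72 and 0.55 with an estimated correlation. The count against tet3 mutants was 179 and 168 without tet3 replicates 1 and 2 and 234 without double mutant replicate 3. It was 600 with only these groups in the fit and 854 with DESeq2. The fit without the 2 shallower tet3 libraries left 1 tet3 library, so it gives no test of the 7 genes named here. gsx1 did not pass with hsp70l as a covariate (log2 change 4.13), or without tet3 replicate 2 or any 1 double mutant library.

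Against tet2 mutants, a comparison also made after the data had been examined, 709 genes differed, 264 higher and 445 lower in double mutants. The count was 66 with only these groups in the fit, 108 with hsp70l as a covariate and 1316 with DESeq2. Endothelial markers had 12 fallers of 22 and no riser (17 adjusted over the list alone; camera adjusted p = 2.7e-17, and adjusted p = 0.3 with an estimated correlation). Pigment markers had 4 risers of 13 (5 adjusted over the list alone; camera adjusted p = 1.1e-05, and adjusted p = 0.78 with an estimated correlation). Muscle markers had 2 fallers of 24 (3 adjusted over the list alone; camera adjusted p = 3.6e-05, and adjusted p = 0.95 with an estimated correlation). Heat shock and immediate early genes had 5 fallers and 1 riser of 28, with 10 and 1 adjusted over the list alone (camera adjusted p = 0.002, and adjusted p = 0.65 with an estimated correlation). Oxidative phosphorylation genes had 0 of 25 members past the limma threshold, also 0 adjusted over the list alone, with a median log2 change of 0.26 (camera adjusted p = 7e-04, and adjusted p = 0.95 with an estimated correlation). socs3b was 3142 ± 1730 against 1134 ± 453 (log2 change 1.4, adjusted p = 0.026 by limma), sox10 3010 against 459 and stat3, the transcription factor gene of this pathway, 1242 against 686. The cardiac genes myl7 and nppa were lower, at 3.51 ± 3.83 against 168 ± 15.6 and 1.55 ± 1.48 against 83.7 ± 35.5. mmp9, a granule protease gene, was 8376 against 1705 (log2 change 2.17, adjusted p = 0.014 by limma). With hsp70l as a covariate socs3b (0.28), stat3 (0.91), nppa (-5.76) and mmp9 (1.34) did not pass, while sox10 (1.95) and myl7 (-7.3) did. socs3b (log2 change 1.4), stat3 and mmp9 did not pass with only these groups in the fit, nor without tet2 replicate 1 or double mutant replicates 1 or 3, and socs3b and stat3 did not pass without tet2 replicate 3. The count against tet2 mutants was 417 without tet2 replicate 3 and 467, 1145 and 377 without double mutant replicates 1, 2 and 3.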

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

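The tests of handling, of a trend with hsp70l, of a general loss of other cell types and of the endothelial share were chosen only after the results were seen, as were the comparisons of tet2 replicate 3 with left-out wildtype libraries and the thinned reads. The interaction test drew attention to 53 genes at which double mutants departed from the sum of the single mutants on the log2 scale. Heat shock transcripts also differed between these groups, so an effect of genotype alone is not shown. The 11 genes named by size of interaction follow. Below the sum of the single mutants were lyve1a (interaction -8.62), cst14b.2 (-6.42), myl7 (-5.92), eef1a1b (-5.24), cdh5 (-4.98), cpb1 (-4.31), edn2 (-4.23), pecam1 (-4.19), clec14a (-4.07) and a gene of the MFAP4 family (-3.97), and MYH6 was above it (5.34). With hsp70l as a covariate pecam1 (-4.16) and MYH6 (5.07) no longer passed. MYH6 also did not pass with a pseudocount of 5, quantile normalization, thinned reads, edgeR, only the groups compared or the replicate block. With single libraries left out MYH6, eef1a1b and pecam1 were each lost in most fits. pecam1 and cpb1 did not pass on thinned reads, and eef1a1b and edn2 did not pass with the replicate block. Of 14 genes named for the interaction 4 passed without tet3 replicate 2 and 6 without tet3 replicate 1 or wildtype replicate 2. By list, the median interaction was -2.24 for endothelial markers, -1.26 for erythroid markers, -0.76 for inflammatory genes and -0.1 for the JAK-STAT list. It was 0.42 for glycolysis, 0.48 for heat shock and immediate early genes, 0.22 for oxidative phosphorylation and 0.24 for ribosomal proteins. None of these 8 lists passed camera with an estimated correlation. Among 100 random assignments of the 12 libraries to the 4 groups, the real one included, 3 gave at least 53 genes. The highest other value was 2088, which points to a structure of the samples that other groupings can pick up.

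Endothelial markers were lower in double mutants than in every other group at 2 dpf. A lower share of every other cell type is argued against by the 2 lists of other cell types that rose, pigment (6 of 13 members rose and none fell) and neural (2 of 23 and none), though by list neither passed with an estimated correlation (adjusted p = 0.38 and 0.91). The neural risers, neurod1 and sox19a, each lost their call in most fits with 1 library left out, so the argument rests mainly on the pigment list. Library depth does not account for the lower endothelial markers either, because on reads thinned to 1 depth the endothelial list still had camera adjusted p-values of 1.3e-09, 4.5e-17 and 6.8e-28 against wildtype, tet2 and tet3 mutants. Fewer endothelial cells or less endothelial RNA among the sorted cells stays open: at least 95.5% of the tested members were below 0 against wildtype, tet2 and tet3 mutants alike, which only restates the pattern. A change in embryos and a change in sorting purity were not separated.

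Heat shock transcripts were lower in double mutants, tet3 mutants and younger wildtype cells than in wildtype at 2 dpf. The list of immediate early and heat shock genes holds mostly immediate early genes. Depth does not account for the fall of this list, with camera adjusted p-values on thinned reads of 0.0011, 5.1e-06 and 2.3e-07 in the 3 groups in this order. A linear trend with the hsp70l level as the whole cause of the double mutant calls is argued against: with that level as a covariate 141 of the 1383 genes were still called in the same direction, among them stab1 (-3.56), lgals3bpb (-5.95) and jak3 (-2.83), while the other calls ended as, over all 1383, the median absolute log2 change went from 1.57 to 1.27 and the median SE from 0.33 to 0.48. For the endothelial markers a heat shock state beyond this trend is argued against by a later comparison. The tet3 mutant hsp70l and hsp70.3 share (0.279 to 0.3%) lay within the double mutant range (0.079 to 1.887%). Yet 6 of 22 markers rose and none fell in tet3 mutants, while 9 fell and none rose in double mutants. Against tet3 mutants 15 were lower, though the list did not pass with an estimated correlation (camera adjusted p = 0.07). For the other calls such a state stays open as the whole cause. The heat shock list kept a camera adjusted p of 0.0083 with the covariate. Being mixed, it does not show that heat shock genes remained lower. Of its immediate early genes jun (-1.18) and fosab (-1.67) still passed with the covariate, and dusp1 (-1.3) and ier5l (1.62) did not. In double mutant replicate 2, the library with most hsp70l, the median change was 0.6 of that in the other double mutants (quartiles 0.31 and 0.9), against 0.28 for hsp70l. The median met the planned bound, but the lower quartile did not and 1 library is too few, a stricter reading adopted after the value was seen. Handling that varied between libraries also stays open, because the 28.4-fold spread of hsp70l within double mutants restates the shares that prompted the question.

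In tet2 mutants the call count depended on replicate 3. The planned test for a mislabelled library decided nothing: over the 85 genes called without it, that library lay nearer to the other tet2 libraries for 34.1%, between the bounds set. A library like the 3 wildtype ones is argued against: that share was 26 points above the highest of 3 left-out wildtype libraries (8.1, 3 and 5.7%), and replicate 3 lay past every wildtype library by more than 1 log2 unit, on the side of the other tet2 libraries, for 32.9% of the 85 genes (13.5, 6.1 and 5.7% for left-out wildtype libraries), with si:dkeyp-85e10.2 at 0 against at least 151.3 and AL935126.1 at 51.44 against 0. Another kind of wrong label, such as a wildtype embryo of the tet2 line, stays open, since over all genes the library correlated more with wildtype (0.95, 0.96 and 0.956) than with the other tet2 libraries (0.885 and 0.94) and lay among wildtype on the first 2 principal components (-50.61 and 38.31). Variants linked to the tet2 locus stay open, with 2% of 100 neighbouring genes and 1.6% of others at p under 0.01 (Fisher exact p = 0.68). Neither si:dkeyp-85e10.2 nor AL935126.1 followed loss of tet2 alone. They averaged 327.4 and 98.08 in tet3 mutants and 268.3 and 60.44 in double mutants.

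For the other comparisons the libraries allow 10 splits, too few for a share under 0.05. In each, 1 split, the real one, reached the real count. The real and highest other counts were 1383 and 0 for double mutants against wildtype, 16 and 0 for tet2 mutants, 1159 and 0 for tet3 mutants, and 3317 and 0 for the wildtype stages. They were 2258 and 14 for double mutants against younger wildtype, 709 and 7 against tet2 mutants, and 372 and 1 against tet3 mutants.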

How the results depend on the processing

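The settings with thinned reads, the shallow tet3 libraries left out, hsp70l as a covariate and double mutants minus tet2 mutants were chosen after the data were seen. Over 168 combinations of a named gene and a comparison, 2926 of 3336 values kept direction and side of the threshold, 367 lost the threshold, 14 gained it and 29 changed sign. With hsp70l as a covariate 67 of the 168 kept both, 94 lost the threshold, 1 gained it and 6 changed sign. The totals include library weights and the fit with 1 tet3 library, neither of which is relied on. Counts in this order are for double mutants, tet2 mutants, tet3 mutants and younger wildtype against wildtype, the interaction, and double mutants against younger wildtype, tet2 and tet3 mutants. The main counts were 1383, 16, 1159, 3317, 53, 2258, 709 and 372. Pseudocounts, filters, TMM, thinning, edgeR and the replicate block kept every count within 1.5 times. DESeq2 gave 2093 for double mutants, 111 for tet2, 236 for the interaction and 1316 and 854 against the single mutants. Quantile normalization gave 32 for tet2. Fits with only the groups compared gave 0 for tet2, 3912 for tet3, and 1150, 66 and 600 for the last 3. With hsp70l as a covariate the counts were 159 for double mutants, 21 for tet3, 41 for younger wildtype, 81 for the interaction, and 1057 and 108 against younger wildtype and tet2. This covariate is confounded with group, so it can also remove group effects: over the 1383 genes the median absolute log2 change went from 1.57 to 1.27 and the median SE from 0.33 to 0.48. Without tet3 replicates 1 and 2 the counts were 47, 2 and 11 for tet3, the interaction and double against tet3 mutants, with fewer libraries. Library weights did not converge and gave 7729, 55, 4005, 7497, 824, 8118, 3342 and 4079, which are not relied on. Leaving out single libraries gave 688 to 1673, 7 to 85, 382 to 749, 1845 to 3316, 14 to 141, 1144 to 2522, 377 to 1145 and 168 to 314. The share of higher genes moved from 39.3 to 21.4% in double mutants and from 50.7 to 76.2% in tet3 mutants with the covariate. It moved from 31.2 to 41.7 and 51.4% in tet2 mutants with edgeR and DESeq2, from 13.2 to 24.1 and 28.8% for the interaction on thinned reads and with DESeq2, from 26.1 to 40.4% against tet3 mutants with DESeq2, and from 54.9 to 40% against younger wildtype with the covariate. With single libraries left out it reached 71.4% in tet2 mutants, 33.3% for the interaction and 15.6% against tet3 mutants.

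For lists in double mutants the 7 calls became 0 with an estimated correlation and 3 with fry, and 7 to 9 with single libraries left out. In the interaction epidermis markers passed as lower on thinned reads (0.022, against 0.064). Ribosomal proteins also passed with the replicate block (0.039) and quantile normalization (7.3e-08), and cell cycle (0.00017), secretory (8.9e-05) and oxidative phosphorylation genes (0.029) passed as lower with the covariate. The similarity of 0.5 became 0.55 with quantile normalization, 0.62 with the covariate and 0.37 with double mutants minus tet2 mutants, and 0.39 to 0.57 with libraries left out. The replicate block gave 1221, 13, 984, 3010, 42, 2041, 645 and 294. Same-number libraries had residual correlations of -0.29 to 0.19 (median -0.01, 6 of 30 over 0.1), and 16 of 60 comparisons were best with their own number, so the numbers do not pair the libraries.

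With the covariate 15 of the 1383 called genes changed sign in double mutants, 29 of 1159 in tet3 mutants, 484 of 3317 in younger wildtype and 1 of 709 against tet2 mutants. Among the named genes, sign changes were in genes not past the threshold, except socs3b in younger wildtype cells (-0.11 with the covariate). With the covariate tet2 was 0.84, 0.02, 1 and 1.29 in double, tet2 and tet3 mutants and younger cells, and tet1 was 1 in younger cells. In double mutants tet1 was -0.01 with TMM, -0.12 on thinned reads and -0.17 with weights, and lyz 0.09 with quantile normalization. In tet3 mutants tet1 was -0.02 with weights and -0.31 without replicates 1 and 2, and lyz 0.34 with quantile normalization. In younger cells tet3 was -0.18 with weights. With single libraries left out, tet2 ranged from -0.91 to 0.13 and tet1 from -0.43 to 0.4 in double mutants, tet2 from -0.22 to 0.01 and lyz from -0.22 to 0.45 in tet2 mutants, tet1 from -0.2 to 0.25 in tet3 mutants, and tet3 from -0.14 to 0.35 and lyz from -0.24 to 0.53 in younger cells. The cause was not tested. The depth of 5.64 and 5.96 M reads limits low genes in tet3 replicates 1 and 2.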

Other observations

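The departures of double and tet3 mutants from wildtype overlapped: 273 genes were higher in both, 264 lower in both and 4 opposite, against 20.1 and 30.1 for independent lists. sox10 rose in both (3010 and 2140 against 298), as did ednrba and cyp4t8, and mcl1a fell in both (9187 and 7041 against 58350). The covariance exceeded that of simulated unchanged groups of equal spread with the same controls by 0.42, and the correlation across genes was 0.64 against a simulated 0.5. With tet2 mutants as the reference for double mutants, so that no library was shared, 123 genes were higher in both, 154 lower in both and 16 opposite, and the correlation was 0.5. This comparison was chosen after the data were seen. The hsp70l and hsp70.3 share was 3.523 to 4.138% in wildtype and 2.182 to 4.884% in tet2 mutants, which served as references. It was 0.279 to 0.3% in tet3 mutants and 0.079 to 1.887% in double mutants, so neither reference separates the overlap from heat shock state. With hsp70l as a covariate ednrba and cyp4t8 passed in neither comparison with wildtype. In that fit sox10 and mcl1a passed in double mutants, but sox10 did not in tet3 mutants.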
